A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

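Ribosome footprints of budding yeast were sequenced in 4 libraries, an input and a streptavidin pulldown from cells given cycloheximide and the same pair from cells without it. Groups were taken from the sample titles, and each group held 1 library. The genotype, the doses and the times are those of the labels.

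Per the file headers, the authors' deposited table gives raw counts, the number of reads mapped to each gene. It also gives RPKM, in which the authors scaled reads to gene length and library size, and the authors' log2 enrichment, the log2 of pulldown RPKM over input RPKM. The authors' calls of enrichment were made by a threshold from a ROC curve, per the file headers. The MitoProt score in the deposited table predicts a mitochondrial presequence, and the annotation of mitochondrial genes and compartments is the authors'. Per the submitters' processing notes, reads were processed with CASAVA and genome build sacCer3. The aligner, the read-length filter and the handling of reads that map to several genes are not given in the sources used here. The table also holds 5 columns of per-sample values for another fusion protein, which were not used here. Library totals worked out from the deposited RPKM exceeded the summed counts, by 13.3% of the total in the input with cycloheximide, 5.72% in its pulldown, 1.46% in the input without the drug and 0.921% in its pulldown.

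The table held 6692 genes, of which 28 are encoded by the mitochondrial genome and 6664 by the nucleus. Of the identifiers, 6008 were found in the reference gene table, which gave coordinates, and 684 were not. All symbols on the fixed lists were found. Of the nuclear genes with a read, 394 had the same counts as another gene in all 4 libraries, of which 4 had at least 100 reads in total, and the reason was not tested.

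Each library was scaled to the sum of its counts over nuclear genes, and a pseudocount of 0.5 reads was added. A comparison used genes with at least 100 reads over its 2 libraries, and a gene was counted as higher or lower at 2-fold or more. Values were centred on the median gene of the comparison for reporting. Intervals of ratios are exact Clopper-Pearson intervals at the 95% level on the pair of counts, and those of the difference between conditions use the normal approximation on the log scale. Reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. Against 0 reads a bound was computed with 3 reads. With 1 library per group no test across genes was made and no p-value is given.

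The comparisons were pulldown against input with cycloheximide, the same without it, the difference of these, and the input with against the input without cycloheximide. There were 30 fixed gene lists: 15 of mitochondrial proteins made in the cytosol (356 genes), 12 of other cell parts (311 genes), dual-targeted enzymes, mitochondrially encoded genes, and the bait and biotin acceptors. The median of each list with at least 5 measured members was ranked among 10000 random lists of its size, matched on deciles of mean input abundance. Separation of mitochondrial from other lists was measured as the area under the ROC curve. The genes named are the 12 most enriched in each condition, the 8 with the largest difference each way, the 5 least enriched in each condition, the 6 highest and 6 lowest in the input ratio, the highest and lowest member of each list in each comparison and up to 2 members nearest its median, and always OM45, RPL16A, RPL16B, OSM1 and the mitochondrially encoded genes. This rule named 367 genes, of which some are printed. The reads of the marker genes MET17, URA3, HIS3 and LEU2, the genes of the closing section that lie outside this rule, and the added lists of targets of the transcription factors Gcn4 and Zap1 and of mitochondrial exon and intron frames, were chosen after the data were seen.

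Alternatives were centring on the median gene or on the genes of the other lists, TMM scaling, a pseudocount of 1, minimums of 20 and 500 reads or 1 read, folds of 1.5 and 4, the authors' deposited log2 enrichment, random lists not matched on abundance, the authors' annotation of mitochondrial genes, and all genes on no mitochondrial list as the comparison. Restriction to genes in the reference annotation and a minimum of 100 input reads in each condition were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and edgeR 4.0.16 in R 4.3.3 for TMM.

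The procedure was tested on simulated data with known folds at the depth of these libraries. Genes were counted there relative to the median gene, so the counts on library totals were not tested. Counting error was the only error simulated, so a share of intervals near 95% was built in, and spread between libraries was not covered. With cycloheximide all 50 genes set 4-fold higher were counted at 2-fold or more, with a median log2 of 2.00. Of 50 genes set 2-fold higher 25 were counted, of 50 set 1.5-fold higher 0, and of 5297 unchanged genes 0. The interval held the true value for 95.4% of genes. Without cycloheximide the values were 50 of 50, 25 of 50, 0 of 50, 0 of 4918 and 95.8%.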

Results

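Proximity-specific ribosome profiling was used to ask which messages were translated next to the mitochondrial outer membrane of budding yeast (Saccharomyces cerevisiae, strain background S288C). The biotin ligase BirA was fused through the fluorescent protein mVenus to Om45, a protein of the outer membrane, and both genes for ribosomal protein Rpl16 carried an Avi tag, the short peptide that BirA biotinylates. A 2 min pulse of 10 nM biotin marked ribosomes close to Om45, and streptavidin then separated the marked ribosomes (pulldown) from a sample of all ribosomes (input). The experiment was done with cycloheximide, an inhibitor of elongation given at 100 µg/ml for 2 min before biotin so that ribosomes stayed on their messages, and without it. Each of the 4 groups held 1 library, so no difference reported here has a replicate check. The listed genes held 22528297 footprint reads in the input with cycloheximide, 37467060 in its pulldown, 18172572 in the input without the drug and 15705022 in its pulldown.

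Enrichment is given as the log2 ratio of pulldown to input after scaling each library to its reads in nuclear genes. With cycloheximide the median gene stood at -0.73 on that scale, and without the drug it stood at -0.03. Values of genes and lists are therefore given relative to the median gene of the same comparison, and the bracketed 95% intervals cover counting error only. Across genes the median interval extended 0.10 log2 units to either side with cycloheximide and 0.15 without. The strain labels were checked against the reads. MET17 (MET15), labelled as deleted, held at most 4 reads in a library and URA3 held 0 in all 4, so these reads fit the labels. The labels also list a BirA gene driven by the PGK1 promoter at the leu2 locus with a LEU2 marker, without giving the species of the marker. LEU2 of the listed genes held 0 reads in both inputs, 1 in the pulldown with cycloheximide and 2 in the pulldown without it. Whether this construct was present was not settled by these reads, and a ligase not tied to Om45 would also mark ribosomes elsewhere, so enrichment is measured for the strain as labelled. HIS3, of which the labelled allele removes only a part, held 6790 reads in the input with cycloheximide.

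With cycloheximide messages for mitochondrial proteins took a larger share of the pulldown than of the input. Nuclear genes that the authors' annotation marks as mitochondrial took 16.6% of nuclear-gene reads in the input (Wilson 95% interval 16.5% to 16.6%) and 42.3% in the pulldown (42.3% to 42.3%). Genes on the fixed mitochondrial lists took 5.71% and 27.7%. The gene with the highest enrichment was MIS1, a mitochondrial enzyme of one-carbon metabolism, at 4.43 above the median gene (4.37 to 4.48). Matrix and inner membrane enzymes, the translation factor TUF1 and the bait OM45 itself, at 4.27 (4.19 to 4.34), followed it. RPL16A and RPL16B, the messages of the tagged ribosomal protein, stood at 0.12 and 0.22.

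Of 5464 genes with at least 100 reads over both libraries, 682 lay at least 2-fold above the median gene and 11 at least 2-fold below it, so 98.4% of the genes past that size were on the higher side. On the planned scale of library totals, without reference to the median gene, 499 genes were at least 2-fold higher and 880 at least 2-fold lower in the pulldown, a higher share of 36.2%. On that scale the shares of a library add to a fixed total, so a larger mitochondrial share lowers the values of other genes. The 880 therefore do not by themselves show messages depleted near Om45. The 12 genes with the highest enrichment spanned mitochondrial metabolism and protein synthesis. DLD1, a lactate dehydrogenase of the inner membrane, stood at 4.37, YME1, an inner membrane protease, at 4.31, TUF1, the mitochondrial elongation factor Tu, at 4.28, and PUT1, the proline oxidase, at 4.25. ARG7 of ornithine synthesis and ATP2, the beta subunit of the ATP synthase, both stood at 4.20. HFA1, the mitochondrial acetyl-CoA carboxylase, stood at 4.18, NFS1, the cysteine desulfurase of iron-sulfur cluster assembly, at 4.16, and RML2, a protein of the mitochondrial ribosome, at 4.13. ADH4, an alcohol dehydrogenase on no fixed list, stood at 4.37 (4.19 to 4.57) on only 245 input reads.

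In genome build sacCer3 these genes lie apart from each other. MIS1 (YBR084W) spans chromosome II from 411054 to 413981, DLD1 (YDL174C) chromosome IV from 145826 to 147589, TUF1 (YOR187W) chromosome XV from 684030 to 685343 and HFA1 (YMR207C) chromosome XIII from 677193 to 683564. OM45 (YIL136W) lies on chromosome IX from 93619 to 94800, and ADH4 (YGL256W) on chromosome VII from 15159 to 16307. All are annotated as protein-coding genes. HFA1 and MIS1 have related genes elsewhere in the genome (ACC1 and ADE3), and how reads shared by such copies were assigned is not given in the sources used here.

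**Figure D1:**
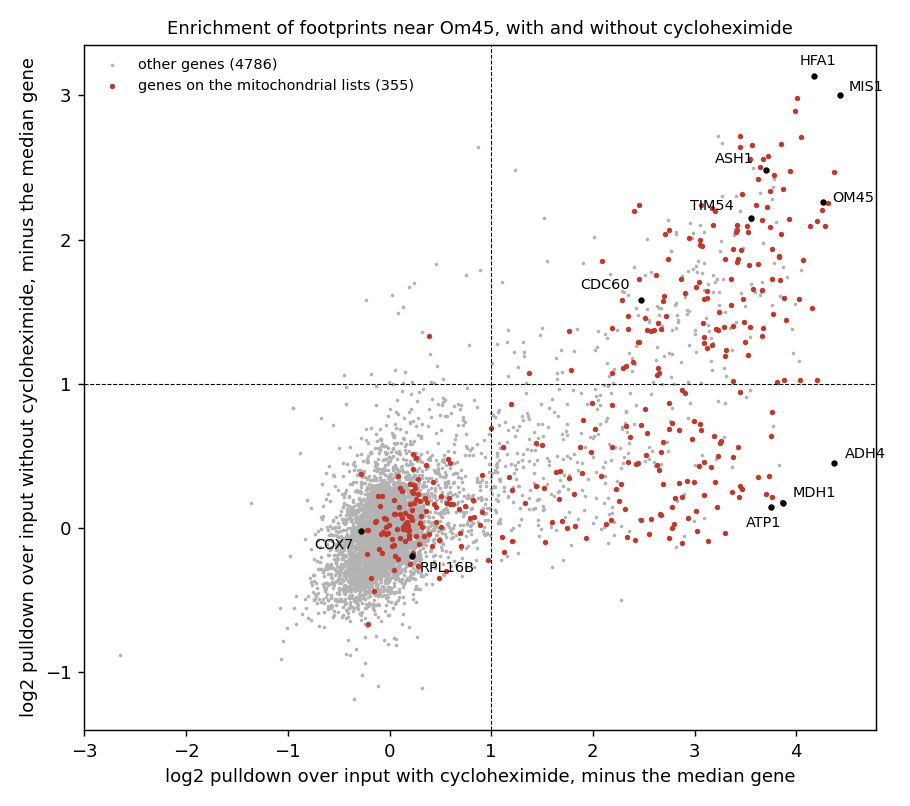
Each point is a nuclear gene with at least 100 reads in both conditions; the x axis gives its log2 pulldown over input with cycloheximide and the y axis the same without it, each minus the median gene, and dashed lines mark 2-fold. Genes on the mitochondrial lists fixed before the data were examined are red, and named genes are black. Genes such as MDH1 (3.87 with, 0.17 without) lie far to the right near 0 on the y axis, while HFA1 (4.18 and 3.13) is high on both.

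Groups of mitochondrial proteins differed in how many members were enriched with cycloheximide. All 17 genes of the TCA cycle and pyruvate dehydrogenase lay at least 2-fold above the median gene, from PDX1 at 2.17 to MDH1, the malate dehydrogenase, at 3.87. So did all 22 genes of amino acid biosynthesis in the matrix, from GCV3, a subunit of the glycine cleavage complex, at 1.52 to MIS1, with a list median of 3.49. Of 24 mitochondrial tRNA synthetases and translation factors 23 did, with DIA4, a seryl-tRNA synthetase, near the middle at 3.38 and YGR102C lowest at 0.60. The list of inner membrane proteases, transporters and assembly factors had 44 of 50 members past that size, among them PCP1, the rhomboid protease, at 3.01, and COX16 lowest at -0.21. Chaperones and proteases of the matrix had 14 of 16, with MDJ1 at 4.03 and HSP10, a short chaperonin subunit, at 0.32. Mitochondrial DNA maintenance had 13 of 15, from MSS116, an RNA helicase, at 3.67 to HMI1, a DNA helicase, at -0.21. Iron-sulfur cluster biogenesis had 11 of 14, with ISD11 lowest at -0.22.

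The shares of the other mitochondrial lists ran from 23 of 29 down to none. Of 29 carriers of the inner membrane 23 were at least 2-fold above the median gene, led by PET9, the main ADP/ATP carrier, at 3.67, with PET8 at the list median of 2.19 and SAL1 lowest at 0.36. Among 19 genes for import and insertion at the inner membrane, 11 were, led by TIM50, a receptor of the TIM23 complex, at 3.85, whereas PAM18 stood at -0.01. Of 26 outer membrane genes 14 were: TOM40, the import channel, stood at 3.17, POR1, the porin, at 1.33, UGO1 at 1.12 and TOM7 at -0.28. The mitochondrial ribosome had 40 of 73 members past that size, from RML2 to MRPL27 at -0.11, with MRPS18 at the list median of 1.68. Of the F1Fo ATP synthase 6 of 15 members passed, including ATP1 at 3.75 and ATP3 at 3.76, while ATP7 stood at 0.14 and ATP20 at -0.09. Of 17 genes of respiratory complexes III and IV 4 passed, with CYT1, cytochrome c1, at 3.88 and COX7 at -0.28. None of the 17 small proteins of the intermembrane space did, and their values ran from MIC14 at -0.19 to TIM12 at 0.36. By contrast, 5 of the 7 intermembrane space proteins made with a presequence did, among them CCP1, cytochrome c peroxidase, at 3.88 and MCR1 at 3.25.

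Genes of other cell parts stayed near the median gene with cycloheximide. None of the 20 cytosolic ribosomal protein genes, 33 genes of ER translocation and folding, 25 vacuolar genes or 18 glycolytic genes was at least 2-fold above it, and the values of glycolytic genes ran from PFK1 at -0.30 to CDC19, pyruvate kinase, at 0.80. Single genes stood out on some lists: CDC60, the cytosolic leucyl-tRNA synthetase, at 2.48, RPN2 of the proteasome at 2.14, RLI1, an iron-sulfur protein of ribosome recycling, at 2.11, the nucleoporin NUP100 at 3.31, the small heat shock protein HSP42 at 2.26 and ERG6 of ergosterol synthesis at 1.41. Among 18 enzymes known from both mitochondria and another compartment, 15 were at least 2-fold above the median gene, and 8 were at least 2-fold higher on library totals. The 15 included LEU4 at 3.92, ALA1 at 1.22 and OSM1, a fumarate reductase, at 1.65, while the glutaredoxin GRX2 stood at -0.17. The 5 genes with the lowest values were short or sparsely read frames. YJL047C-A stood at -2.65 (-3.16 to -2.19) on 271 input and 43 pulldown reads, followed by YMR119W-A at -1.36, YER138W-A at -1.34, YHR007C-A at -1.27 and YIL100C-A at -1.08.

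Without cycloheximide fewer genes lay at least 2-fold above the median gene. The annotated mitochondrial share of reads was 20.2% in the input (Wilson 95% interval 20.2% to 20.2%) and 23.6% in the pulldown (23.6% to 23.6%). Genes on the fixed mitochondrial lists took a smaller share of both, 4.46% of the input and 7.60% of the pulldown. Between the inputs the 2 sets went opposite ways, the annotated share being higher without the drug and that of the fixed lists lower. HFA1 stood at 3.13 above the median gene (2.97 to 3.31), MIS1 had an interval of 2.96 to 3.05, and MGM1, the dynamin-like GTPase of inner membrane fusion, stood at 2.98 (2.90 to 3.06). YME2, an inner membrane protein, stood at 2.89, SUV3, an RNA helicase of the mitochondrial degradosome, and ATP22, a translational activator, at 2.72, and YTA12, a subunit of the m-AAA protease, at 2.71. CCM1 stood at 2.67, MEF1, the mitochondrial elongation factor G, at 2.66, MDL2, an ABC transporter, at 2.65, and ATM1, the exporter that serves cytosolic iron-sulfur proteins, at 2.64. OM45 stood at 2.26 (2.13 to 2.40), RPL16A at -0.10 and RPL16B at -0.19. The highest value, 4.13 for YMR013W-A, rested on 96 pulldown and 6 input reads and had an interval of 3.07 to 5.72.

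Of 5148 genes with enough reads, 329 lay at least 2-fold above the median gene and 4 at least 2-fold below it. On library totals the numbers were 312 and 4. The 4 low genes were ATG12, YDR132C, WSS1 and GLG1, and the next lowest was MDM1. GLG1 stood at -1.19 (-1.72 to -0.69) on 122 input reads, and MDM1 at -0.94.

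The groups ranked differently from the set with cycloheximide. Among mitochondrial tRNA synthetases and translation factors 21 of 24 were at least 2-fold above the median gene, with DIA4 near the list median at 1.94 and MEF1 highest, while PET112 stood at 0.00. The list of inner membrane proteases, transporters and assembly factors had 32 of 50, with CRD1, the cardiolipin synthase, near the middle at 1.38. Carriers had 16 of 28, from CRC1 at 2.20 to AGC1 at -0.30. Import and insertion at the inner membrane had 9 of 19, led by TIM54 at 2.15, the outer membrane 8 of 26 and the presequence class of the intermembrane space 4 of 7. Matrix amino acid biosynthesis had 12 of 22: LEU9 stood at 2.14 and SHM1, a serine hydroxymethyltransferase, at 1.48, against -0.09 for ILV3. None of the 17 TCA cycle genes passed, and their values ran from KGD1 at -0.07 to ACO1, aconitase, at 0.80. The mitochondrial ribosome had 15 of 73, led by MRPL3 at 2.14, matrix chaperones and proteases 6 of 16, led by OCT1 at 2.22, DNA maintenance 7 of 15 and iron-sulfur cluster biogenesis 4 of 14, led by IBA57 at 2.04. The ATP synthase had 1 of 15, ATP2 at 1.03, and complexes III and IV 1 of 17, CYT1 at 1.03. None of the 17 small intermembrane space proteins did. Of 17 dual-targeted enzymes 4 did, led by PIF1, a DNA helicase, at 2.19.

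Outside mitochondria, CDC60 at 1.58, NUP170 at 1.81, RPN2 at 1.14, TIR1, a cell wall mannoprotein, at 1.22, the Hsp70 gene SSA3 at 1.83, NUP100 at 1.05 and POT1, a peroxisomal thiolase, at 1.01 were among the genes at least 2-fold above the median gene without cycloheximide. No member of the lists for cytosolic ribosomal proteins, glycolysis, ER translocation, ergosterol and lipid synthesis, vacuole or ribosome biogenesis was.

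**Figure D2:**
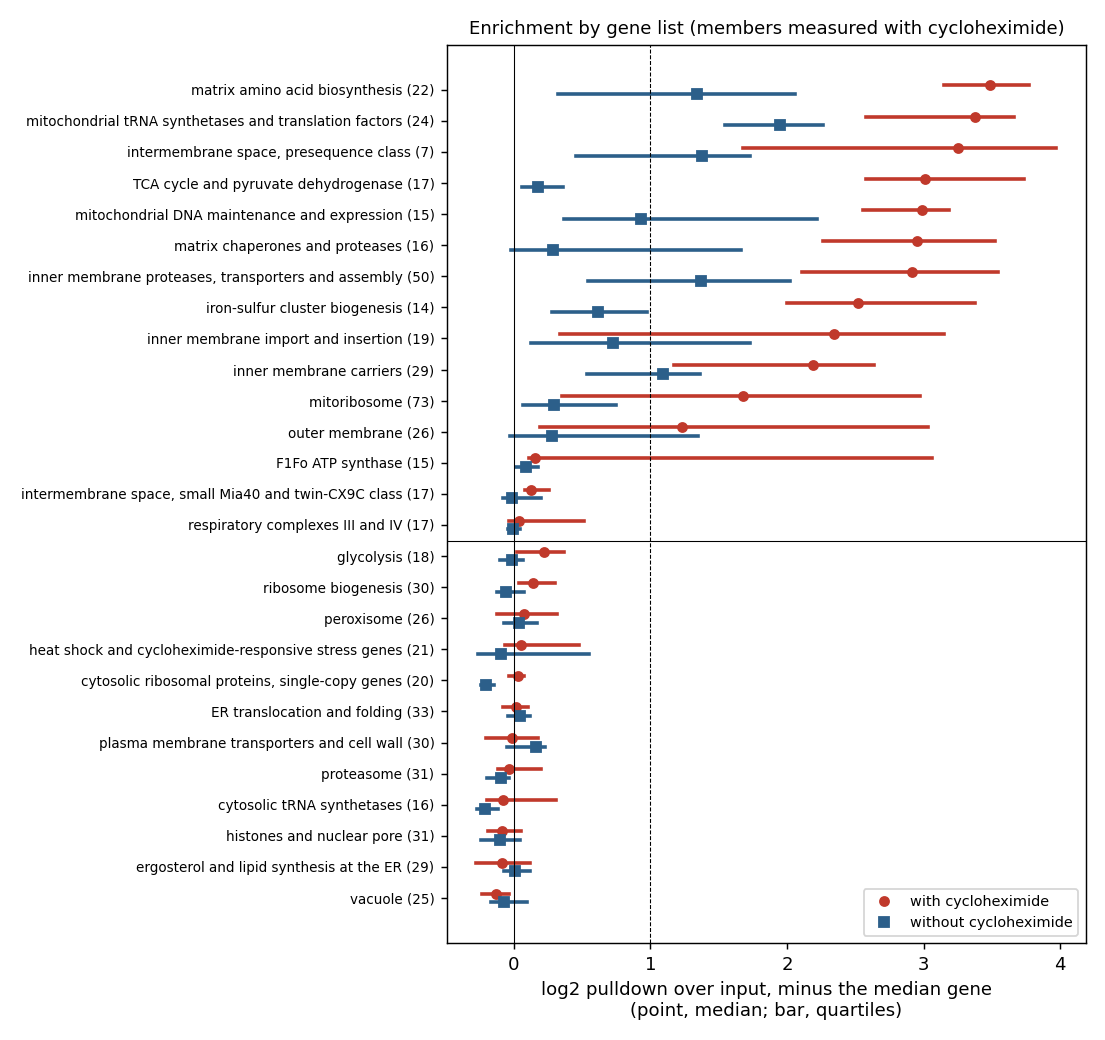
For each gene list fixed before the data were examined, the point gives the median and the bar the quartiles of its members' log2 pulldown over input minus the median gene, with cycloheximide (red circles) and without (blue squares); numbers in brackets are members measured with cycloheximide, the solid vertical line marks the median gene, the dashed line 2-fold, and the horizontal line parts mitochondrial from other lists. The TCA cycle list has a median of 3.01 with and 0.17 without cycloheximide, and the list of tRNA synthetases and translation factors 3.38 and 1.95.

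The direct comparison of conditions asked which messages were more enriched with cycloheximide than without it. With 1 library per group, the drug and the state of the cultures cannot be told apart as sources of a difference. The 8 largest differences, with minus without, belonged to ADH4, MDH1, CIT1, ATP1, ATP3, BAT1, ALD4 and SDH1. Relative to the median gene, whose difference was -0.65, MDH1 stood at 3.66 (3.58 to 3.73), CIT1, citrate synthase, at 3.64 (3.60 to 3.68), ATP1 at 3.56, ATP3 at 3.50, BAT1, a branched-chain aminotransferase, at 3.42, ALD4, an aldehyde dehydrogenase, at 3.35, and SDH1, a subunit of succinate dehydrogenase, at 3.33. ADH4 had the highest value, 3.88 (3.69 to 4.07). The input of ADH4 itself differed between conditions, with 245 reads with and 20468 without the drug. For CIT1 the reads were 22420 in the input and 327914 in the pulldown with cycloheximide, and 11689 and 11211 without.

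Of 5141 genes measured in both conditions, 492 had a difference at least 2-fold above the median gene and 32 at least 2-fold below it, a higher share of 93.9%. On library totals, where the same limit of a fixed total applies, the numbers were 234 and 693, a higher share of 25.2%. All 17 TCA cycle genes had a difference at least 2-fold above the median gene, from IDH2 at 1.59 upward, with a list median of 2.82, and so did all 22 genes of matrix amino acid biosynthesis, with a list median of 2.05. Other lists had smaller shares: 13 of 16 matrix chaperones and proteases, among them SSC1, the matrix Hsp70, at 3.29 and HSP60 at 2.94; 20 of 24 tRNA synthetases and translation factors, led by RRF1 at 2.37; 40 of 73 genes of the mitochondrial ribosome, led by PET123 at 2.83; 16 of 28 carriers; and 14 of 26 outer membrane genes, led by MCR1 at 2.62. Iron-sulfur cluster biogenesis had 10 of 14, led by NFU1 at 3.18, and the inner membrane list had 32 of 50, led by COQ5, a methyltransferase of coenzyme Q synthesis, at 2.97. Import genes ranged from SOM1 at -0.98 to MDM38 at 2.01. On library totals fewer members had a difference of at least 2-fold. TCA cycle genes had 16 of 17, matrix amino acid biosynthesis 16 of 22 and matrix chaperones and proteases 11 of 16. The tRNA synthetases and translation factors had 6 of 24, the mitochondrial ribosome 29 of 73 and carriers 5 of 28. The outer membrane had 5 of 26, iron-sulfur cluster biogenesis 7 of 14 and the inner membrane list 15 of 50.

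The genes at the other end had few reads without cycloheximide. They were YGR067C at -1.86 (-2.48 to -1.24), PAU17, a seripauperin, at -1.82, YML045W and YML045W-A at -1.82, YJL047C-A at -1.81, SIP18 at -1.64, YMR119W-A at -1.58 and YBL005W-A at -1.56. The pair YML045W and YML045W-A overlap and hold identical counts in all 4 libraries, and YBL005W-A overlaps another frame, so their reads cannot be assigned to a single gene.

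Among genes measured in both conditions, 668 were at least 2-fold above the median gene with cycloheximide and 328 without it. They shared 303, where independent lists of these sizes would share 42.6. The authors' annotation marks 195 of the 303 as mitochondrial, 168 of the 365 found with cycloheximide alone and 2 of the 25 found without it alone. Across genes, which are not independent replicates, the enrichments had a Pearson correlation of 0.765 and a Spearman correlation of 0.553. The authors' deposited table calls 404 genes enriched with cycloheximide and 223 without. Of these, 209 are called in both conditions by the authors' deposited table, 182 with the drug and not without it, and 14 the reverse.

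By the compartments in the authors' annotation, 70.0% of 190 matrix genes and 69.3% of 153 inner membrane genes were at least 2-fold above the median gene with cycloheximide, against 27.9% and 48.4% without. The shares were 46.2% and 23.1% for 26 outer membrane genes, and of 25 intermembrane space genes 7 and 4 passed. Among 4069 genes with no mitochondrial annotation the shares were 4.47% and 1.67%.

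As a description of these libraries, each list's median was ranked among 10000 random lists of its size, matched on mean input abundance. Of 15 mitochondrial lists 12 lay above the central 95% of random lists in each condition. The exceptions were the same in both: complexes III and IV at percentiles 82.6 with and 67.2 without cycloheximide, the ATP synthase at 96.5 and 96.0, and the small intermembrane space proteins at 89.1 and 32.1. Among other lists, glycolysis stood at 99.6 and ribosome biogenesis at 99.03 with cycloheximide on medians of 0.22 and 0.14, and plasma membrane and cell wall genes at percentile 99.99 without it on a median of 0.16. The remaining lists had medians between -0.13, for the vacuole, and 0.07, for the peroxisome, with cycloheximide. Without it, cytosolic ribosomal proteins had a median of -0.20 and cytosolic tRNA synthetases of -0.21, at percentiles 0.76 and 0.85. In the difference between conditions plasma membrane and cell wall genes had a median of -0.20, below all 10000 random lists. The vacuole, at -0.12 (percentile 1.22), and ergosterol and lipid synthesis, at -0.10 (percentile 2.16), also lay below the central 95%. Ribosome biogenesis, at 0.135 (percentile 98.12), lay above it. Enrichment ranked genes of the mitochondrial lists above genes of the other lists with an area under the ROC curve of 0.899 with cycloheximide (bootstrap 95% interval over genes 0.872 to 0.921) and 0.832 without (0.802 to 0.860).

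The comparison of the inputs asked how footprints of all ribosomes differed with cycloheximide. Relative to the median gene, most genes of ribosome biogenesis and glycolysis lay at least 2-fold lower with the drug, but on library totals 10 of 30 and 7 of 18 did. The input ratio also fell with abundance. Its median, relative to the median gene, ran from 1.30 in the lowest decile of input reads without the drug to -0.94 in the highest. Those reads are also the denominator of the ratio, so part of the fall is built in, and how much was not tested. Each decile held 428 or 429 genes, so the deciles did not cover all 5380 genes of the comparison. The lowest genes were ADH4, VEL1, YOR387C and ZPS1, and the highest were sparsely read frames. ADH4 stood at -7.43 relative to the median gene (-7.62 to -7.25), on 245 reads with and 20468 reads without the drug, VEL1 at -7.43, YOR387C at -6.65 and ZPS1, a zinc-regulated secreted protein, at -6.46 (-6.54 to -6.38). YBL039C-A at -3.00 and IMD4 of GTP synthesis at -2.90 completed the lowest 6. At the other end, YER175W-A had 863 reads with cycloheximide and 0 without, at least 139-fold higher relative to the median gene when 3 reads are allowed for the 0. YER138W-A had 104 and 0, at least 16.8-fold higher on the same scale. YGR045C stood at 5.91, YKR073C at 5.75, YEL045C at 5.51 and YGL006W-A at 5.46 (3.54 to 11.36), on 1 to 7 reads without the drug.

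The median gene was 1.67-fold higher in the input with cycloheximide, a log2 value of 0.74. Relative to it, 568 of 5380 genes were at least 2-fold higher and 560 at least 2-fold lower, a higher share of 50.4%. On library totals 1875 were higher and 115 lower, a share of 94.2%, so only lists whose median lies more than 0.74 below the median gene are below 0 on that scale.

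Against random lists matched on abundance, ribosome biogenesis had a median of -1.45 (below all 10000 random lists). Of its 30 genes 24 lay at least 2-fold below the median gene, against 10 at least 2-fold lower on library totals. RRP5, a pre-rRNA processing factor, stood at -2.70. Glycolysis stood at -1.58 (percentile 0.01), with ENO1 at -2.21, and the stress list at -1.16 (percentile 0.1), with the chaperones HSP82 at -2.68 and HSC82 at -2.40 but catalase CTT1 at 1.33. Matrix amino acid biosynthesis had a median of 0.04, which exceeded most matched lists (percentile 99.87). Of the other mitochondrial lists 4 lay above the central 95%: carriers with a median of 0.53 and iron-sulfur cluster biogenesis with 0.34, both at percentile 99.4, complexes III and IV with 0.01 at 98.9 and the mitochondrial ribosome with 0.11 at 97.8. The other 10 lay within the central 95%, lowest for tRNA synthetases and translation factors and highest, at 91.2, for inner membrane proteases and related genes, with the TCA cycle at 41.0 on a median of -0.67. In matrix amino acid biosynthesis 6 of 22 genes were at least 2-fold higher, led by ARG7 at 2.38, and 2 lower, with SHM1 at -1.95. Cytosolic ribosomal protein genes stood at -1.10 (percentile 3.63) and cytosolic tRNA synthetases at -1.13 (percentile 2.37). The peroxisome list stood at 0.37, with PXA2, a fatty acid transporter, at 2.51, and among carriers CRC1, the carnitine carrier, at 3.73. Dual-targeted enzymes ranged from ALA1 at -1.74 to CAT2, carnitine acetyltransferase, at 2.67. OM45 stood at 0.44 (0.30 to 0.58), RPL16A at -1.07 and RPL16B at -1.69.

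**Figure D3:**
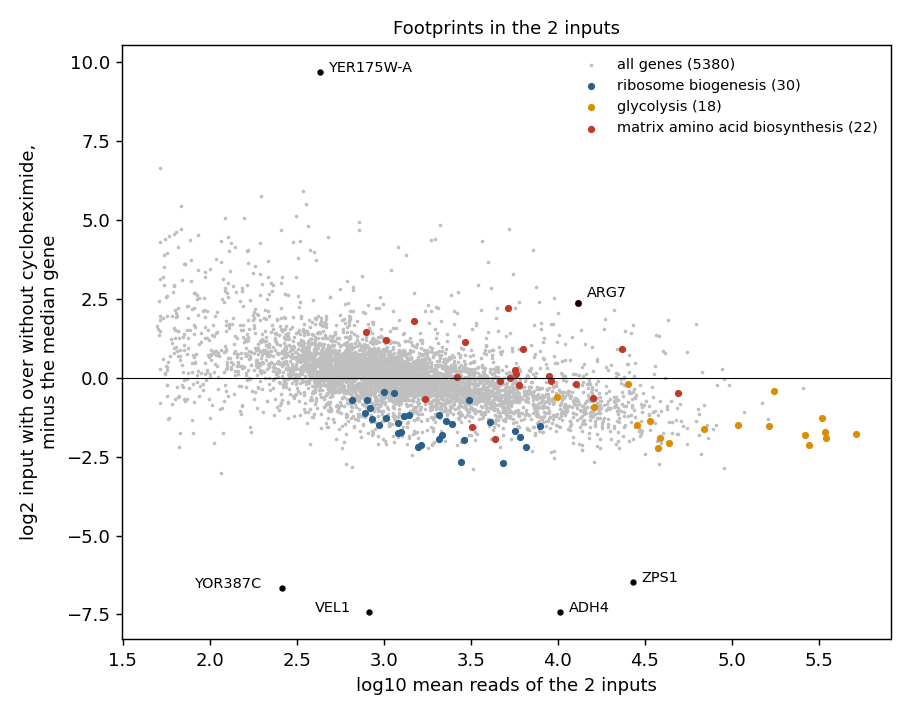
Each point is a nuclear gene; the x axis gives log10 of its mean reads in the 2 inputs, and the y axis its log2 input with over without cycloheximide, minus the median gene. Coloured points are members of 3 lists fixed before the data were examined; YER175W-A had 0 reads without the drug and its height depends on the pseudocount. Ribosome biogenesis genes lie below 0, ARG7 lies at 2.38, and ADH4, VEL1, ZPS1 and YOR387C lie between -7.43 and -6.46.

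Genes encoded in the mitochondrial genome, which are translated by mitochondrial ribosomes inside the organelle, had few reads and lie outside the nuclear comparisons. COX1 held 47 reads in the input and 32 in the pulldown with cycloheximide, and 18 and 62 without. COX2 held 26, 11, 17 and 30 in the same order, COX3 31, 11, 4 and 21, COB 23, 17, 13 and 30, ATP6 40, 10, 13 and 16, OLI1 16, 11, 5 and 5, VAR1 8, 4, 3 and 0, and ATP8 3, 0, 1 and 4. In all 28 mitochondrial frames together the pulldown held 317 reads and the input 317 with cycloheximide, and 412 and 106 without it.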

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

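The test of counting error below was chosen only after the result was seen, and the test of frames outside the reference annotation before it. Among the named genes, 16 lay on opposite sides of 0 in the enrichments with and without cycloheximide, with counting intervals that exclude 0 under both scalings, and with 1 library per group these differences were not tested. Values are the difference, with minus without cycloheximide, relative to the median gene. It was 3.29 for SSC1, 3.18 for ILV3, 2.94 for HSP60, 2.78 for KGD1 and 1.87 for GLR1, which lay above 0 with cycloheximide and below 0 without it. The reverse held for YBL005W-A at -1.56, YML045W and YML045W-A at -1.82, HMG1 at -0.84, TOM7 at -0.69, ZPS1 at -0.50, SPC3 at -0.43, GRX2 at -0.41, MRPL27 at -0.38, GAS5 at -0.28 and CPS1 at -0.18.

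The library total worked out from the deposited RPKM of the input with cycloheximide exceeded the counts of the listed genes by 13.3% of that total, and whether these are reads outside the genes or a different total was not tested.

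Mitochondrially encoded frames, which no comparison of nuclear genes used, had a log2 pulldown over input of 2.20 (1.89 to 2.52) relative to the median nuclear gene without cycloheximide, and -0.01 with it. Without the drug, frames within introns held 244 pulldown and 32 input reads and exon frames 168 and 74, an odds ratio of 3.35 with an exact 95% interval from 2.08 to 5.49, which argues against counting error of few reads for the reads as assigned; COX1 and COB overlap the intron frames within them in the reference, so how shared reads were split is not known and the odds ratio depends on it. With cycloheximide the odds ratio was 3.68 (2.61 to 5.21), with intron frames at 0.86 and exon frames at -1.02, so the excess of intron over exon frames was present in both conditions. Untranslated RNA carried into the pulldown would raise other frames that are not known genes, but their median without the drug was 0.139 (0.0128 to 0.263) over 43 frames, below the 0.5 that a general carry-over was set to need, though the interval reaches above the bound of 0.2 set against it. These frames are nuclear and do not test RNA from inside the organelle, so this explanation stays open for the mitochondrial frames, and no biological explanation was tested. The Avi tag was on Rpl16, a protein of cytosolic ribosomes, so the value of 2.20 does not measure mitochondrial ribosomes marked by the ligase.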

How the results depend on the processing

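All alternatives were chosen before the data were examined except the restriction to reference genes and to 100 input reads in each condition, chosen after seeing the data, which left each count within 1.5 times. No paired analysis was possible because each group held 1 library and the labels give no replicate numbers; for the same reason nothing could be left out in turn and no other split made. No named gene at 2-fold or more changed sign. The other scalings shift every gene by the same amount, less than 2-fold, so they could not reverse such a gene and are no check of its sign. The balance of higher to lower genes turned over with scaling in the comparison with cycloheximide, the difference and, under TMM, the inputs. With cycloheximide the 499 higher genes became 281 at 4-fold; the 880 lower became 11 when centred on the median gene, 11 with TMM, 11 when centred on the other lists, 3671 at 1.5-fold, 4 at 4-fold and 444 from the authors' deposited enrichment. Without it the 312 higher became 513 at 1.5-fold and 71 at 4-fold, and the 4 lower became 26 at a minimum of 20 reads, 0 at 500, 57 at 1 read, 73 at 1.5-fold and 0 at 4-fold. For the difference, the 234 higher became 492 centred on the median gene, 521 with TMM, 483 centred on the other lists, 386 at 1.5-fold and 45 at 4-fold; the 693 lower became 32, 23 and 34 under the same scalings, 447 at a minimum of 500 reads, 3001 at 1.5-fold, 16 at 4-fold and 367 from the authors' deposited enrichment. For the inputs, the 1875 higher became 568 centred and 525 with TMM, and the 115 lower 560 and 618. Changes with fold, centring and read minimum follow from how these were built. TMM added the same amount to the log2 ratio of each gene: 0.72 with cycloheximide, -0.01 without it and -0.79 for the inputs. The authors' log2 enrichment lay a median of 0.12 above the planned value with cycloheximide and 0.01 above it without. Their RPKM was scaled to larger library totals, by 13.3% of the total in the input with cycloheximide and 5.72% in its pulldown, which raises that enrichment. The area under the ROC curve without cycloheximide, 0.832, was 0.782 with the authors' annotation and 0.794 against all genes on no mitochondrial list; the cause was not tested. Of 6313 alternative values of named genes, 3491 moved beyond their counting interval, 3013 of them by centring or TMM. None of 224 list medians at other read minimums moved beyond its bootstrap interval; other scalings shift every list by the same amount, so that the ATP synthase with cycloheximide stood at 0.15 relative to the median gene and -0.57 on library totals. Under the alternatives run for them, 11 or 12 of 15 mitochondrial lists lay above the central 95% of random lists. Depth limits the genes under 100 reads, which have no reported ratio.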

Other observations

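The tests below were chosen only after the results were seen, except that of read depth, and the genes of the next paragraph were chosen after their values were seen.

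The authors' deposited table marks 36 genes as enriched with cycloheximide and without mitochondrial annotation. Of these, 24 were also at least 2-fold above the median gene without the drug. Among all genes at least 2-fold above it with cycloheximide and measured in both conditions, 303 of 668 were. The 36 were selected for high values with the drug and the enrichments correlate across genes, so recurrence partly follows from the selection. A MitoProt score of at least 0.5 was held by 12 of the 36. The share over all genes was not worked out, so this number shows no excess. ASH1, a repressor of mating-type switching, stood at 3.70 with and 2.48 without cycloheximide, and RAD2, a nuclease of DNA repair, at 3.58 and 2.49. SIR4, a silencing factor, stood at 3.37 and 1.24, HAP1, a haem-responsive activator, at 2.77 and 1.92, and SNF2, the ATPase of a chromatin remodeller, at 2.35 and 1.21. NPR2 and NPR3, partners in a complex that regulates TORC1, stood at 2.53 and 2.33 with cycloheximide, and at 2.01 and 0.81 without it. MET6, methionine synthase, stood at 2.43 and 1.53.

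Among 355 genes on the mitochondrial lists, enrichment without cycloheximide increased with protein length (Spearman's rho across genes, which are not independent replicates, 0.575, bootstrap interval 0.487 to 0.659), from a median of 0.06 in 69 genes of up to 150 amino acids to 2.10 in 38 genes of 601 to 900. The 11 genes of 901 or more stood at 0.72. A bias of counting with length would also raise long genes elsewhere, but over 4069 genes with no mitochondrial annotation rho was -0.173 (-0.202 to -0.143); rho was at least 0.493 within each tercile of input reads, and 0.472 (0.358 to 0.572) among proteins of at least 150 amino acids, which argues against read depth and against the shortest proteins alone. Longer reading frames may give a nascent chain more time at the surface before synthesis ends, but enrichment with cycloheximide also increased with length (0.721), and given it the partial rho was 0.0867 (-0.0494 to 0.219), which leaves this hypothesis open.

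In the input with cycloheximide, targets of the activator of amino acid biosynthesis Gcn4 had a median of 1.54 relative to the median gene. Of these targets 12 of 19 were at least 2-fold higher. Targets of the zinc-responsive activator Zap1 had a median of -1.67, with 10 of 14 at least 2-fold lower. Both lists were chosen after the data were seen. The Zap1 list holds ADH4, VEL1, YOR387C and ZPS1, the lowest genes of the input comparison, so its values partly restate them. GCN4 itself stood at 2.88 (2.78 to 2.98), HIS4 at 1.88, SNZ1 at 2.95 and the zinc transporter ZRT1 at -2.74, while LYS9 stood at -0.97 and ZRT2 at 0.97. A general rise of low-abundance genes was examined in 3 ways. The Gcn4 list lay at percentile 100 of random lists matched on abundance. It was chosen after its values were seen, so this percentile does not count against such a rise. The median percentile of abundance of its members in the input without cycloheximide, the denominator of the ratio, was 76.3 (43.4 to 87.2). Subtracting the median of other genes in the same decile of abundance raised the Gcn4 median to 1.93 (0.76 to 2.30) and left the Zap1 median at -1.20 (-4.33 to -0.67). Both of these last intervals exclude 0. They describe the genes chosen, and since both lists were chosen after their values were seen, they do not test whether the trend accounts for the shifts. For the Gcn4 targets the trend ran the other way: decile 8 of abundance had a median of -0.40, and the lowest decile 1.30. That removing it raised their median argues against the trend as a source of their rise. Their interval reaches below the 2-fold bound set for them before this last test, so a size of 2-fold is not settled. No bound was set for the Zap1 targets, whose median moved toward 0, so a contribution to their fall stays open. Across 4272 genes with no mitochondrial annotation the ratio of the pulldowns followed that of the inputs (Spearman's rho 0.894, 0.885 to 0.903). In the pulldowns the Gcn4 median was 1.28 and the Zap1 median -1.61, though ADH4 stood at -3.56 there against -7.43 in the inputs. The rho and these medians argue against an error in a single input library. The drug and the state of the culture cannot be told apart for the Zap1 median of -1.67, since each condition came from 1 input library.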
